A study of Mus musculus with 8 samples.

How the data were processed

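Tumors of FC1242 cells were compared between the pancreas and the liver. FC1242 is a mouse pancreatic cancer line. Per the labels, 100000 cells were injected into C57BL/6 mice, either into the pancreas or so that tumors formed in the liver, and tumors were harvested after 3 weeks. Bulk RNA-seq was made from 3 primary pancreatic tumors and 3 liver metastatic tumors, with total RNA from fresh tissue taken up on QIAGEN RNeasy Mini columns and standard Illumina libraries. CD45+ cells sorted from tumors of each site gave 1 10x single-cell library per site, so 8 samples were used. The labels give no sex, batch, strandedness or pairing of mice, and name bcl2fastq, Cell Ranger and mm10 without saying which data each was used for. The aligner and the counting tool of the bulk libraries are not stated.

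The authors deposited 3 bulk tables for the same 6 libraries. The first table deposited by the authors holds raw read counts, whole numbers per gene symbol. The second deposited table holds normalized signal: each raw count divided by 1 factor per library, and the factors equal median-of-ratios size factors of the raw counts. The third table deposited by the authors holds FPKM, which equals the normalized value divided by 1 constant per gene. The single-cell matrices deposited by the authors hold UMI counts for every barcode of the reagent kit, 6794880 barcodes and 31053 genes per library, with no selection of cells. The labels name 3' v2 reagents, whose barcode list is shorter than the list in the files; the kit version was left open.

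Bulk totals ran from 27481400 to 36743200 reads per library. Of 52459 genes listed, 16487 passed filterByExpr and were tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, a robust quasi-likelihood fit on group alone, a two-sided test and Benjamini-Hochberg adjustment at 0.05. CPM of tested genes use TMM-scaled totals, and CPM of genes the filter removed use plain totals. The closing section is the exception, where all bulk CPM use TMM-scaled totals. The 44 gene lists were fixed before the data were examined, and so were the rule for named genes, the cell type markers and the first filters on cells. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, with fry and with camera at an estimated correlation beside it. Named genes were the 6 largest changes in each direction among called genes whose groups did not overlap and whose mean was at least 5 CPM, up to 3 called members of each list by p-value, the most abundant members of the hepatocyte, acinar and islet lists, and a fixed set. A fold against a group at 0 reads was set against 3 reads over the group and is a lower bound. On simulated counts with the spread of these libraries, 100 genes changed by 1 on the log2 scale gave 16 calls and 100 changed by 2 gave 80. Both sets were part of the same run of 16218 tested genes, in which 4 unchanged genes were called. The changed genes had a mean of at least 1 CPM, and no other gene was changed. The real comparison called 3787 genes, so the adjustment was stricter in the simulation. Its counts therefore do not give the share of real changes that was found. The replicate numbers were tested as pairs: deviations from the group mean correlated at -0.18, 0.25 and 0.09 between libraries of the same number, so the libraries were not treated as paired.

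Single-cell matrices were read with scipy 1.17.1 and analysed with scanpy 1.11.5, leidenalg 0.10.2 and scikit-learn 1.9.0 (Python 3.11.15). A called cell had at least 1500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. The UMI minimum first fixed was 500; it was raised after the liver library showed a peak of barcodes around 668 UMIs, since a minimum of 500 would have called 52400 cells there and 2583 in the primary library. Scrublet (expected rate 6%) marked 5 of 2277 primary and 70 of 7618 liver barcodes, which were removed. Cells of both libraries were scaled to 10000 UMIs, log-transformed, and clustered together on 2000 variable genes and 30 principal components with 15 neighbors and Leiden resolution 1, with no integration. Clusters led by T or NK markers were split again. A cluster took the name of the class whose markers had the highest mean fold over the other clusters, given at least 3 markers more than 2-fold higher and seen in 10% of its cells; the score needed was lowered from 0.5 to 0 after cluster 5 had stayed unnamed. That cluster holds 578 primary and 9 liver cells and scored 0.27 as monocyte or macrophage. The authors' own cell annotation was not used here.

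With 1 library per site no test was run on cells. UMIs of a class were summed and given as CPM with exact Poisson intervals, and shares with exact (Clopper-Pearson) binomial intervals, both at 95% and for counting error only. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. A count of 0 was read as allowing 3. Genes of a class with at least 50 cells per library were named by size: the 5 largest ratios in each direction at 50 CPM or more in the higher library with intervals apart, and a fixed set. Barcodes with under 100 UMIs gave a profile of free RNA. In the liver library the peak of barcodes lay around 668 UMIs, and in the primary library around 237 UMIs. Both lie above that limit, so the profile may not show the free RNA of called cells. No free RNA was subtracted from any class. Classes of low depth are the most open to it, such as liver neutrophil-like cells (median 2086 UMIs). In the primary library the free RNA profile held Alb at 550 CPM, while 1504 monocyte or macrophage-like cells there held 1 Alb UMI. The profile was therefore not taken as the background of shares, and other classes were set beside a share in its place. It still served as a cut: a gene named by size had to reach its level in the profile of the higher library. Mitochondrial, ribosomal protein, Xist, Tsix, Y-linked and antigen receptor variable-segment genes were left out of that naming. On simulated sums, all 200 genes changed 4-fold were recovered, and 269 unchanged genes also had intervals apart, which non-overlap alone does not exclude. The simulation held counting error only, with changed genes at 50 CPM or more and totals near those of T cell-like cells. It does not cover spread between animals, nor a class with far fewer UMIs such as B cell-like cells.

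Alternatives for the bulk results were RLE factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 libraries, TMM without the hepatocyte, acinar and islet lists, FPKM and normalized values in limma, glmTreat at a fold of 2, the replicate number as a block and leaving out each library. For the single cells they were UMI minimums of 300, 500, 1000 and 3000, mitochondrial maximums of 5% and 20%, doublets kept, Leiden resolutions of 0.5 and 2, libraries clustered apart, and thinning to 500 or 2000 UMIs or none. TMM without genes over 100-fold higher, the UMI minimums of 500 and 3000, a naming score over 0.5 and B cells by 3 markers were added after the data were seen. The check of leading genes against a cluster's name was set to folds over clusters of other names after the data were seen. In the closing section, 1 bound on different tumor cells was for a time widened after its value was known and was then put back as first written; the use of its exact interval was also chosen after its value was known. Tests on Xist alone and on Epcam alone at each site were added after their values were seen. Gene positions are from GENCODE vM21 on GRCm38. Figures were drawn with matplotlib 3.10.9.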

Results

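Tumors grown from FC1242 pancreatic cancer cells in the pancreas and in the liver of mice were profiled by bulk RNA-seq, with 3 libraries per site, and by single-cell RNA-seq of sorted CD45+ cells, with 1 library per site. The bulk libraries held 32326000, 27481400 and 33156500 reads for the primary tumors and 28513800, 36743200 and 34398900 for the liver tumors. The single-cell libraries held 82083967 UMIs (primary) and 161890665 UMIs (liver) over all barcodes. The title of the series asks about B cells that carry BTLA and CD200, a pair of immune inhibitory proteins, and about immune cells that differ between metastatic and primary tumors. The comparison of the sites answers which genes and cell types differed between them.

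Liver tumors carried the transcripts of liver tissue. All 29 tested hepatocyte genes were higher in the liver tumors, with a median log2 change of 10.69, among them Alb (serum albumin; 12.19, SE 0.87) and Hpx (hemopexin; 7.29, SE 0.67). The hepatocyte list took 12.6%, 12.2% and 8.07% of the reads of the 3 liver libraries and 0.0524%, 0.0955% and 0.0934% of the primary ones. The 6 largest rises were in Slc26a1, Bhmt2, Adh4, Mug-ps1, Sec14l4 and Cyp2c37, which had 0 reads in all 3 primary libraries and were at least 5067-, 4569-, 4406-, 3914-, 3842- and 2837-fold higher (3 reads over the group as the floor). Bile acid and drug-metabolism genes (16 of 17 higher, median 10.87), such as the bile salt exporter Abcb11 (13.05, SE 0.52), rose with them. Of the complement and acute-phase genes, 19 of 23 were higher and 1 (Lbp) was lower, with a median of 5.0. Genes of resident liver cells were higher too: all 15 of the Kupffer cell list (median 3.83), such as Cd5l (9.03, SE 0.45), and all 12 of the liver sinusoidal endothelial list (median 3.11, also with Clec4g at its bound). The Kupffer cell list shares Cdh5 with the endothelial list and Folr2 and Cd163 with the macrophage list. In the single-cell libraries, cluster 18, led by Cd5l, held 38 primary and 103 liver cells, so Cd5l was not confined to the liver library. Clec4g, at 0 reads in the primary libraries, was at least 2408-fold higher. Stellate and smooth muscle genes (9 of 15 higher, median 1.56), such as the vitamin A enzyme gene Lrat, and endothelial genes (10 of 17, median 0.87), such as Kdr (2.01, SE 0.23), also rose. These 7 lists were called at a preset correlation; with an estimated correlation the adjusted p was 0.369 for the hepatocyte, bile acid, complement and Kupffer lists, 0.375 for the sinusoidal and stellate lists and 0.407 for the endothelial list.

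B-cell genes were higher in liver tumors. Of 22 tested members of the B-cell list, 17 rose and 0 fell in edgeR (1 fell at an unadjusted p under 0.05 and in DESeq2, 0 in limma-voom), with a median log2 change of 2.56; 20 rose and 1 fell when adjusted over the list alone. Ms4a1 (CD20) went from 0.193 ± 0.0641 CPM to 2.48 ± 1.20 CPM (SD, n = 3 per site; log2 change 3.66, SE 0.52, adjusted p = 0.00159). Cd79a of the B-cell receptor rose by 4.36 (SE 0.50) and Ighd, the IgD heavy chain of mature naive B cells, by 3.63 (SE 0.46). The call at the preset correlation was lost with an estimated one (adjusted p = 0.369), and under the filter of 5 CPM (adjusted p = 0.0757), which left few of these low genes. Levels of these 3 genes stayed under 7 CPM in every library. Of 16 plasma cell genes 4 rose, among them Mzb1 and Iglc2, and the list was not called (adjusted p = 0.0607).

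Btla, an inhibitory receptor of lymphocytes and dendritic cells, rose from 2.37 ± 1.11 to 10.1 ± 2.04 CPM (SD, n = 3 per site; log2 change 2.08, SE 0.39, adjusted p = 0.00653), with every liver library above every primary one. Cd200, which signals through the CD200 receptor to myeloid cells, did not pass: 8.85 ± 1.68 CPM in primary and 4.58 ± 1.33 CPM in liver tumors (log2 change -0.95, SE 0.31, adjusted p = 0.0641). Its receptor Cd200r1 (1.36, SE 0.44, adjusted p = 0.0565) and Tnfrsf14, the ligand of BTLA (1.24, SE 0.45, adjusted p = 0.0834), did not pass either. Cd200r1 and Tnfrsf14 passed without primary replicate 2 (log2 changes 1.65 and 1.84), and all 3 passed in DESeq2, with adjusted p-values of 0.0219, 0.0107 and 0.0259. Btla lies on chromosome 16 at 45224315 to 45257670 and Cd200 on the same chromosome at 45382135 to 45409053 (GRCm38). The regulatory B-cell list had 4 of 25 members higher and 2 lower and was not called (adjusted p = 0.507); its clearest member, Cd1d1 (5.37, SE 0.36), is also made by hepatocytes.

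**Figure D1:**
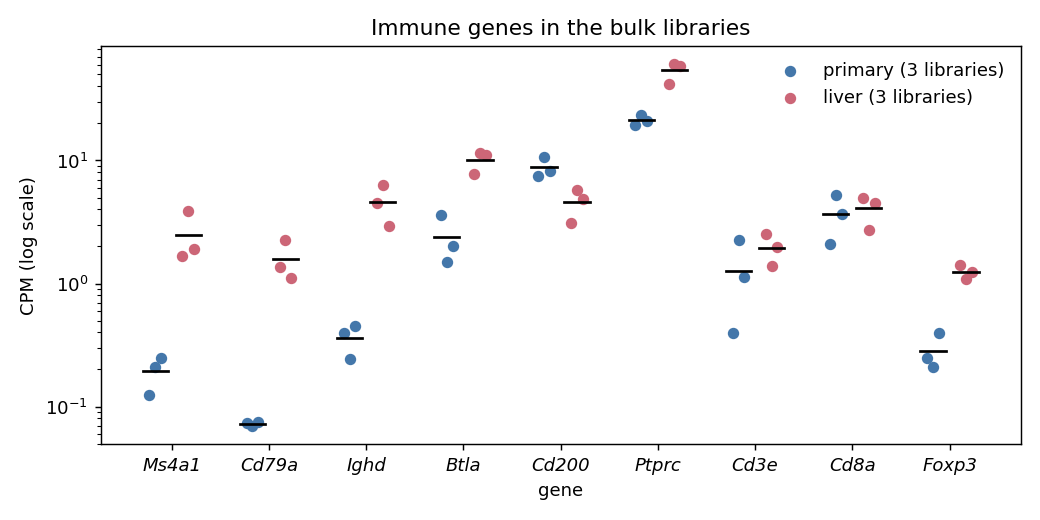
Points give CPM on a log scale for 9 immune genes in the 3 primary and 3 liver bulk libraries, and black lines give group means. Ms4a1, Cd79a, Ighd, Btla, Ptprc and Foxp3 were higher in every liver library, while Cd3e and Cd8a overlapped between sites.

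Ptprc (CD45) rose from 21.2 ± 2.05 to 53.9 ± 10.4 CPM (log2 change 1.35, SE 0.20). Of 20 T-cell genes only Zap70, a kinase of T-cell receptor signaling, was called in edgeR (1.96, SE 0.37), with 5 at an unadjusted p under 0.05, 2 called in DESeq2 and 1 in limma-voom; Cd3e (0.65, adjusted p = 0.464) and Cd8a (0.16, adjusted p = 0.811) were not. The T-cell list was called narrowly (median 0.64, adjusted p = 0.0493; 0.572 with an estimated correlation) and lost its call without primary replicate 1 (median 0.41) or liver replicate 1 (median 0.40), with the replicate number as a block (adjusted p = 0.0584) and on log2(FPKM + 1) and log2(FPKM + 0.1) (0.0651 and 0.0556). With the filter of 5 CPM its direction turned (median -0.12, adjusted p = 0.661). Of the regulatory T-cell genes 4 of 10 rose, with Foxp3 at 2.11 (SE 0.41), and 1 (Capg) fell, and the list was not called (adjusted p = 0.190). None of 15 cytotoxic genes passed in edgeR (2 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom; adjusted p of the list 0.586). Of 17 NK and innate lymphoid genes 5 rose, such as Klrk1 (2.22, SE 0.36), and Gata3 fell; the list was called (median 0.79, adjusted p = 0.0292; 0.369 with an estimated correlation), and not without primary replicate 1 (median 0.70, adjusted p = 0.0504), on log2(FPKM + 1) (0.0616) or with the filter of 5 CPM (0.519).

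The dendritic, antigen presentation, interferon response and macrophage lists were called as higher at a preset correlation. With an estimated correlation the adjusted p was 0.375 for the dendritic, 0.378 for the antigen presentation, 0.407 for the interferon and 0.677 for the macrophage list. Dendritic genes (17 of 24 higher, median 1.18) included H2-Ab1, an MHC class II chain (1.31, SE 0.18), and Irf8 (1.36, SE 0.19). Antigen presentation genes (14 of 20, median 1.25) included the immunoproteasome subunit Psmb8 (1.89, SE 0.21) and H2-Q7 (2.98, SE 0.26). Interferon response genes (11 of 28, median 0.84; 15 when adjusted over the list alone) included Iigp1 (3.87, SE 0.28) and Stat2 (1.54, SE 0.26). Macrophage genes (12 of 24 higher, Cd14 lower, median 0.79) included Adgre1 (F4/80; 1.66, SE 0.25), Folr2 (3.63, SE 0.39) and Arg1 (4.61, SE 0.43), which is also a urea cycle enzyme of hepatocytes. The monocyte gene Ccr2 rose by 2.19 (SE 0.36), in a list that was not called (7 higher and 4 lower of 18, adjusted p = 0.158). Of the higher macrophage genes, Folr2 and Cd163 are also in the Kupffer cell list and Mrc1 in the sinusoidal endothelial list. C1qa and C1qc are also in the complement list, and Arg1 in the hepatocyte list. The macrophage rise is therefore not separate from the rise of those lists. The macrophage list was not called without primary replicate 3 (median 0.58, adjusted p = 0.0977). The chemokine Cxcl1 rose by 4.23 (SE 0.45), but the myeloid chemokine list did not move as a whole (3 higher and 1 lower of 20, adjusted p = 0.982).

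The ductal and tumor epithelium, hypoxia and acinar lists were called as lower in the liver tumors at a preset correlation. With an estimated correlation the adjusted p was 0.407 for the epithelial, 0.436 for the hypoxia and 0.553 for the acinar list. Of 25 ductal and tumor epithelium genes 9 fell (15 when adjusted over the list alone, where 1 rose), with a median log2 change of -0.97 (-0.61 without primary replicate 2); Msln (mesothelin) fell from 350 ± 56.4 to 127 ± 18.2 CPM (-1.46, SE 0.22) and Cd24a by 1.40 on the log2 scale (SE 0.22). Krt19 did not pass (-1.21, adjusted p = 0.0686) except without primary replicate 1 (-1.48). Of 21 hypoxia and glycolysis genes 9 fell (median -0.86, and -0.51 without primary replicate 2), among them Pfkl (-0.95), Car9 (-1.45) and Ddit4 (-1.71). Without liver replicate 2 these 3 had adjusted p-values of 0.0878, 0.0834 and 0.0959, and without liver replicate 1 Car9 and Ddit4 had 0.0742 and 0.0762. Of 31 acinar genes in the counts only 7 passed the filter, so the list call rests on these 7. Of them 3 fell (median -1.64), among them the elastase gene Cela1 (-1.69, SE 0.19) and Reg1 (-4.18, SE 0.60). Without primary replicate 2 the median was -0.58 and the list was not called (adjusted p = 0.172). Without liver replicates 1 or 3 the median was -2.56 or -2.63. None of 27 cell cycle genes passed in edgeR, DESeq2 or limma-voom or had an unadjusted p under 0.05 in edgeR (adjusted p of the list 0.304). The largest falls were in Chga, Chgb, Cyp11a1, Dlk1 and Cyp21a1 (log2 changes -9.42, -9.15, -7.67, -7.15 and -4.25), where Chga and Chgb encode proteins of secretory granules and Cyp11a1 and Cyp21a1 enzymes of steroid hormone synthesis. All 5 stood highest in primary replicate 1, with Chga at 76.8 CPM there and 2.22 and 0.970 CPM in the other primary libraries, and without that library the changes were -5.34, -3.57, -3.26, -3.22 and -2.69. The calls of the first 4 ended without any of liver replicates 1, 2 or 3, while that of Cyp21a1 stayed.

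**Figure D2:**
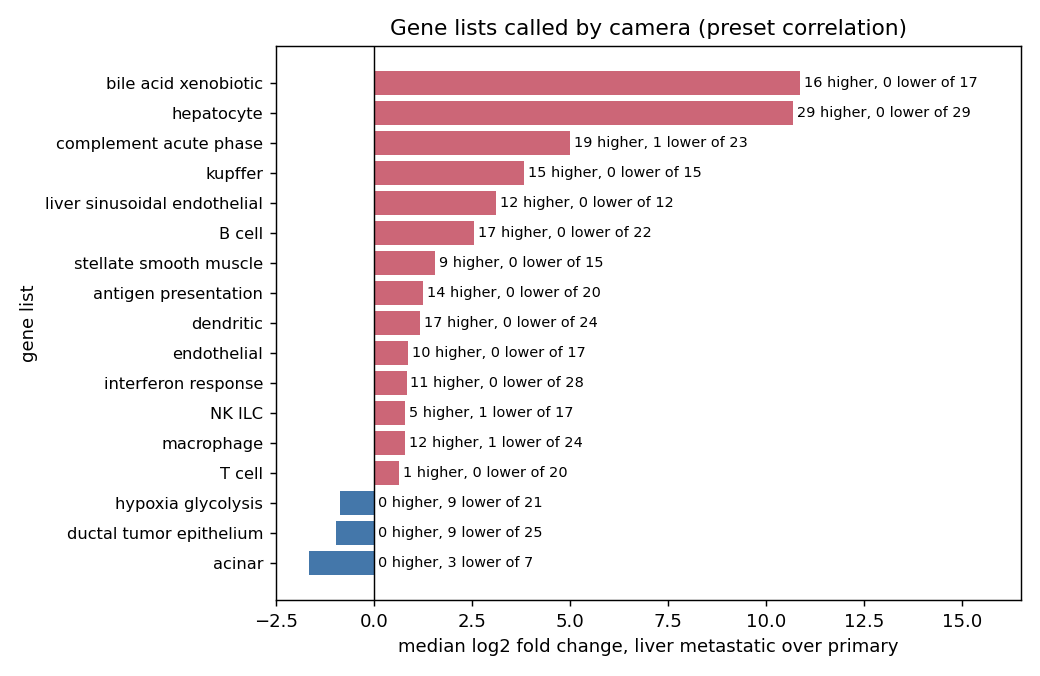
Bars give the median log2 fold change, liver over primary, of the 17 lists called by camera at the preset correlation, with counts of called genes beside them. Liver lists lead at 10.87 and 10.69, the B-cell list lies at 2.56, and 3 lists lie below 0.

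Of the 44 lists, 27 were not called, with adjusted p-values from 0.0565 to 0.982. Among tissue lists, islet genes had 1 member higher (Ttr, also made by liver) and 4 lower of 6, cholangiocyte genes 3 lower of 10, fibroblast genes 8 higher and 1 lower of 24, and erythroid genes 2 higher of 9. The mesenchymal list had 2 of 16 higher, the mesothelial list 1 higher and 2 lower of 10, the adipocyte list 2 of 7 higher, the nerve list 1 higher and 1 lower of 5, the skeletal muscle list 1 of 3 lower and the extracellular matrix list 2 of 28 higher. Among immune lists, CD4 helper genes had 4 higher and 1 lower of 8, gamma-delta T genes 1 of 5 higher, neutrophil genes 3 of 18 higher, plasmacytoid dendritic genes 5 higher and 1 lower of 11, mast cell genes 2 higher and 4 lower of 14, and suppressive myeloid genes 5 higher and 1 lower of 18. The neutrophil members were G0s2, Wfdc21 and Hdc (not called without liver replicate 1 or 2), and S100a8 did not pass (0.11, adjusted p = 0.878). Checkpoint genes had 6 higher and 3 lower of 33, with Cd274 (0.45, adjusted p = 0.284) and Pdcd1 (0.39, adjusted p = 0.568) not passing, and lymphoid chemokines 6 higher and 1 lower of 13. Dissociation stress genes had 3 of 17 lower and housekeeping genes 2 higher and 1 lower of 15. In 21 of the 44 lists the count differed when adjusted over the list alone, by at most 7 genes. The mesothelial median was 1.03 while camera gave its direction as down, and median and mean differed in sign for the mesenchymal, nerve, myeloid chemokine and housekeeping lists.

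Over all genes, 2755 of 16487 were higher in liver tumors and 1032 lower in the edgeR test, and 6051 had an unadjusted p under 0.05. Of the rises, 519 were over 100-fold, and 144 called genes had 0 reads in the primary tumors. Fewer genes were called as lower without liver replicate 2 (134), liver replicate 1 (414) or primary replicate 3 (606), and fewer as higher without liver replicate 2 (1810). With the replicate number as a block 2703 were higher and 873 lower, and the T-cell and acinar lists were not called (adjusted p = 0.0584 and 0.0516). All 17 list calls were lost with an estimated correlation, where 4 of the 44 lists had an unadjusted p under 0.05. The hepatocyte list, with all 29 tested genes higher, lost its call there too. The calls of that run therefore do not separate weak lists from strong ones. All 17 passed in fry, which does not compare a list with other genes.

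In the single-cell libraries 2272 primary and 7548 liver cells were called, with medians of 12031.5 and 6748 UMIs per cell, in 37 clusters. Monocyte or macrophage-like cells made up 1504 primary cells (66.2%, 95% interval 64.2% to 68.1%) and 3065 liver cells (40.6%, 39.5% to 41.7%). At a naming score over 0.5, as first written, cluster 5 is left unnamed and these shares were 40.8% (926 cells) and 40.5% (3056 cells), so the gap rests on that cluster; over leukocytes they were then 69.2% and 78.1%. At UMI minimums of 300 and 500 the liver share was 6.00% and 6.14%, with 90.5% and 74.9% of liver cells unnamed. Epithelial tumor cell-like cells, which a CD45 sort should leave out, made up 14.3% (325 cells) and 46.7% (3528 cells); the primary share was 8.93% at a UMI minimum of 3000 and 8.58% with libraries clustered apart. Over leukocytes alone, the share of monocyte or macrophage-like cells was 78.5% and 78.1%, that of neutrophil-like cells 11.5% and 13%, and that of dendritic cell-like cells 3.29% and 3.34%. These shares also rest on cluster 5, as most of its cells are primary. With it unnamed, neutrophil-like cells (220 and 511) made up more of the primary than of the liver leukocytes. T cell-like cells were 6.47% (5.41% to 7.66%) of primary and 3.64% (3.08% to 4.28%) of liver leukocytes. NK-like cells were 12 in the liver library and 0 of 2272 in the primary one, which allows a share of up to 0.132%. Sort, yield and the mitochondrial limit can each set these shares: 58.5% of primary and 39.1% of liver barcodes of at least 1500 UMIs exceeded 10% mitochondrial UMIs. The remaining cells were 15 acinar-like, 13 fibroblast-like, 2 erythroid-like and 1 mast cell-like cell in the primary library, and 91 erythroid-like, 15 mast cell-like and 5 fibroblast-like cells in the liver library.

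**Figure D3:**
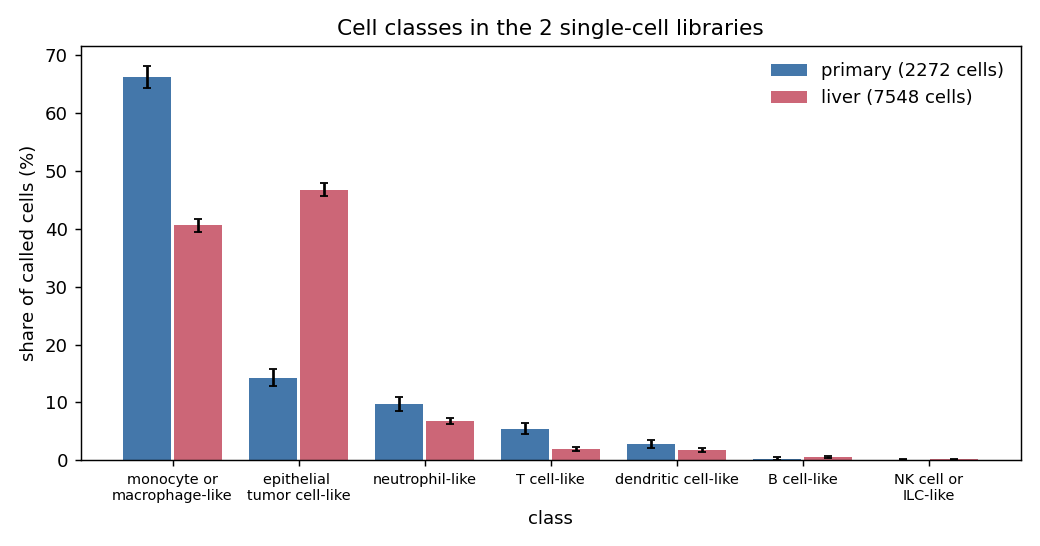
Bars give each class as a share of called cells in percent for the primary (2272 cells) and the liver (7548 cells) library, with exact 95% binomial intervals that cover counting error only. B cell-like cells were 0.220% and 0.623%, and epithelial tumor cell-like cells 14.3% and 46.7%.

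B cell-like cells (cluster 24, led by Igkc, Cd79a and Ms4a1) were 5 of 2272 primary cells (0.220%, 0.0715% to 0.513%) and 47 of 7548 liver cells (0.623%, 0.458% to 0.827%). Of leukocytes they were 0.261% (0.0847% to 0.608%) and 1.20% (0.881% to 1.59%), intervals that do not overlap, whereas those over all called cells do. Over all called cells the direction turned at a UMI minimum of 300, with 6 of 2774 primary and 40 of 53546 liver cells. With UMI minimums of 1000 and 3000 the liver share stayed the higher, by a smaller gap. At 1000 UMIs per cell, 5 of 47 liver B cell-like cells (10.6%, 3.55% to 23.1%) and 1 of 5 primary ones had a Btla UMI, and 2 of 47 and 0 of 5 a Cd200 UMI. The liver Btla share was 26.1% at 2000 UMIs and 38.3% without thinning, and at 1000 UMIs ran from 5.13% at a UMI minimum of 300 to 17.4% at 3000. No B cell-like cell had both, which allows up to 6.38% in the liver and 60% in the primary library for cells with UMIs of both at 1000 UMIs, not for cells that express both. Without thinning, 4 of 47 (8.51%) and 1 of 5 had both, at medians of 3022 and 6497 UMIs. At Leiden resolution 2, 1 of 49 liver cells had both at 1000 UMIs, and at 2000 UMIs 1 of 5 primary cells did. Monocyte or macrophage-like cells, taken as the background, had Btla in 0.0653% of liver and 0.133% of primary cells at 1000 UMIs, at medians of 10926 and 13811.5 UMIs, and Cd200 in 0 of 3065 and 0.0665%. Dendritic cell-like cells had Btla in 5.34% of liver and 12.7% of primary cells at 1000 UMIs, Cd200 in 7.63% and 6.35%, and both in 1 of 131 and 1 of 63. Without thinning, 12.2% and 25.4% of them had both, at medians of 7789 and 24458 UMIs. T cell-like cells had Btla in 2.10% of liver and 0.806% of primary cells at 1000 UMIs, and Cd200 in 3.50% and 8.06%. Their Cd200 shares without thinning were 17.5% and 32.3%, at medians of 5854 and 10806 UMIs. Cd200 was therefore not particular to B cell-like cells. With 5 primary cells, a difference between sites in the share with both genes was not detectable at this depth. Summed over B cell-like cells, Ighd was 359 CPM in the liver library (78 UMIs) and 59.6 CPM in the primary one (3 UMIs; ratio 6.02). Cd9, a tetraspanin, was 64.4 CPM (14 UMIs) and 496 CPM (25 UMIs). The suppressive cytokine Il10 had 0 UMIs in both.

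In monocyte or macrophage-like cells, Spp1 (osteopontin) was 376 CPM in primary and 3916 CPM in liver cells, a ratio of 10.4, Lpl (lipoprotein lipase) 43.4 and 463 CPM, Gpnmb 30.7 and 266 CPM, and the monocyte attractant Ccl2 103 and 685 CPM. Trem2 was 316 and 633 CPM, Arg1 1937 and 2768 CPM and Ccr2 263 and 467 CPM, but at a naming score over 0.5 the log2 ratio of Arg1 was -0.00035. The opposite held for the T-cell attractant Cxcl9 (523 and 68.8 CPM), nitric oxide synthase Nos2 (38.1 and 4.62 CPM), Cd274 (PD-L1; 171 and 37.9 CPM), H2-Ab1 (5685 and 2257 CPM), Vegfa (213 and 26.7 CPM) and Il1b (334 and 126 CPM). In the bulk libraries Cxcl9 and H2-Ab1 went the other way and were called as higher in the liver tumors, while Arg1 and Ccr2 were higher in both. The reason for the disagreement was not tested. The growth factor gene Tgfb3 had the largest ratio downward (92.6 and 4.13 CPM), followed by Pde4b (161 and 8.01 CPM). C1qa (4559 and 4001 CPM) and Apoe (ratio 0.937) were close. Most of these cells lay in clusters 5, 8 and 10 in the primary and 0, 4 and 6 in the liver library, so site and library cannot be separated; Gpnmb, Lpl, Ccl2 and Spp1 were among the leading genes of cluster 0, and Nos2, Tgfb3 and Vegfa among those of cluster 10.

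**Figure D4:**
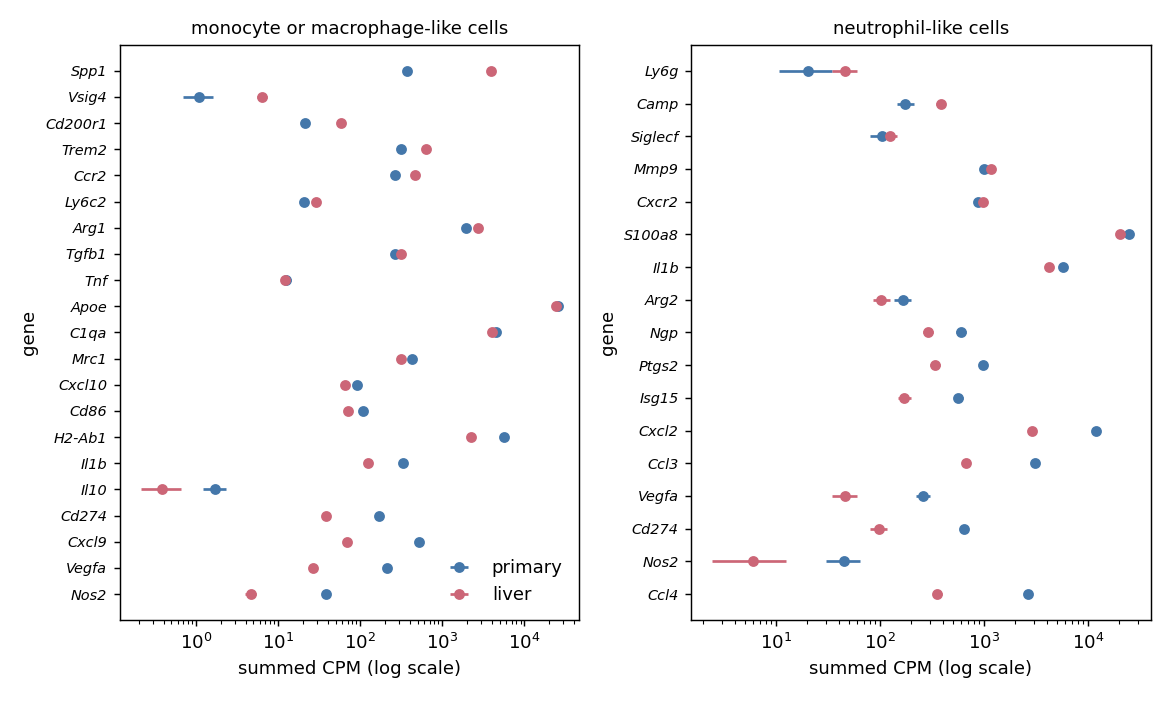
Points give summed CPM on a log scale with exact 95% Poisson intervals (counting error only) for the fixed genes with at least 3 UMIs in both libraries, in monocyte or macrophage-like and in neutrophil-like cells. Spp1 lies at 376 CPM in the primary and 3916 CPM in the liver library, and Cd274 at 171 and 37.9 CPM.

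In neutrophil-like cells (cluster 14 in primary, 7 in liver), Ccl4 was 2644 CPM in primary and 355 CPM in liver cells, Ccl3 3066 and 674 CPM, and Cxcl2 had a ratio of 0.246. Cd274 (641 and 97.2 CPM), Ptgs2 (971 and 338 CPM) and Vegfa (257 and 46.0 CPM) were lower too, while Cxcr2 overlapped (866 and 977 CPM). The largest ratio upward in liver neutrophil-like cells among genes named by size was that of Tff1 (51.1 and 1532 CPM). The free RNA profile of the liver library held Tff1 at 1510 CPM, just under the 1532 CPM of these cells, and the source of this RNA was not tested. Liver neutrophil-like cells had a median of 2086 UMIs, and the peak of liver barcodes lay around 668 UMIs. Free RNA may therefore shift the ratios of this class, which was not tested.

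T cell-like cells (mostly parts of cluster 20 in primary and of cluster 15 in liver) had granzyme A, Gzma, which leads cluster 15.3, at 109 CPM in primary and 1256 CPM in liver cells. The checkpoint receptor Ctla4, which leads cluster 20.1, was 171 and 35.5 CPM, Lag3 320 and 213 CPM, Gzmb 272 and 164 CPM and perforin, Prf1, 234 and 147 CPM. Pdcd1 (256 and 250 CPM) and Ifng (106 and 88.8 CPM) overlapped. At 1000 UMIs, Cd8a was seen in 54.8% (45.7% to 63.8%) of primary and 35.7% (27.8% to 44.1%) of liver T cell-like cells, at medians of 10806 and 5854 UMIs, and Cd4 in 1.61% and 4.90%. At UMI minimums of 300 and 500 the log2 ratios of summed CPM turned for Cd8a (0.69 and 0.60) and Cd4 (-1.44 and -0.76). Without thinning, the Cd8a shares were 89.5% and 70.6%, and monocyte or macrophage-like cells had Cd8a in 0.0665% and 0.0979% at 1000 UMIs.

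Dendritic cell-like cells lay mostly in cluster 16 (59 of 63 primary and 102 of 131 liver cells), led by Xcr1 and Clec9a of cross-presenting dendritic cells. Cluster 25, led by Ccr7, Fscn1, Ccl22 and Il12b of migratory dendritic cells, held 4 primary and 29 liver cells, and over the class Ccr7 was 64.6 and 498 CPM and Il12b 18.1 and 140 CPM. Cyp26b1, which breaks down retinoic acid, was 296 and 73.8 CPM, and the interferon-induced gene Rsad2 70.0 and 10.2 CPM. Cxcl10, also interferon-induced, went the other way, with 2 UMIs (1.21 CPM) in primary and 110 UMIs (102 CPM) in liver cells, a ratio whose counting interval is 22.7 to 703. Xcr1 was 426 and 352 CPM, and Clec9a overlapped (301 and 260 CPM).

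Epithelial tumor cell-like cells (clusters 1, 2, 9 and 11 in primary, 1, 2 and 3 in liver) held Gkn1 (28.1 and 654 CPM), Gkn2 (38.9 and 642 CPM), Phgr1 (44.8 and 374 CPM), Lgals2 (83.0 and 601 CPM) and Tff1 (867 and 5167 CPM) higher in the liver library, except that Tff1 turned at a UMI minimum of 300 (log2 ratio -0.33). Adm, a hypoxia-induced peptide (114 and 4.42 CPM), Lcn2 (101 and 4.17 CPM), Cited1 (201 and 9.58 CPM) and Wfdc18 (99.3 and 0.570 CPM) were lower. Gkn1, Gkn2 and Tff1 were among the leading genes of cluster 3, which held 699 liver cells and 1 primary cell. These genes were chosen by size under the cuts given above, among them the free RNA profile, and no free RNA was subtracted.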

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

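The signal below was looked for after the share of called B cells was known, and no test of an explanation was run on it. Barcodes over the mitochondrial limit of 10% are outside the report's comparisons. In the liver library, 10 of 4881 such barcodes (0.205%, exact 95% interval 0.0983% to 0.376%) held UMIs of at least 3 B-cell markers, above the 3 barcodes that a count of 0 allows. Of liver barcodes over 10% and up to 20% mitochondrial, 7 of 1623 (0.431%) did. In the primary library it was 1 of 3210 (0.0312%) and, from 10% to 20%, 1 of 735 (0.136%), and among called cells 7 of 2272 (0.308%) in the primary and 40 of 7548 (0.530%) in the liver library. No biological explanation was tested.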

How the results depend on the processing

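Of 118 named bulk genes that were called, 65 kept direction and call in every alternative run that tested them. The filter of 5 CPM tested 88 of the 118, and a gene left out of a run was not counted as losing its call there. Of the 17 called lists none kept the call in every run, since all 17 lost it with an estimated correlation (0 higher, 0 lower). Even the hepatocyte list, with all 29 tested genes higher, was not called there (camera, adjusted p = 0.369). A call lost in that run therefore does not separate weak lists from strong ones. The B cell-like values rest on 5 and 47 cells, and the shares with Btla or Cd200 on 1000 UMIs per cell, a depth at which a gene can be missed. Where no cause is given below, the cause was not tested.

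Genes called as higher numbered 1510 with a fold of at least 2 and 1810 to 3346 with 1 library left out; genes called as lower 57, 1567 in DESeq2, and 134 to 1468 with 1 library left out. A fold of at least 2 is a stricter test by construction. Without a filter, which adds low genes, 22 lists were called as higher and 6 as lower, and with 1 library left out the lists called as lower numbered 4 to 5 in place of 3. List medians or camera directions turned as follows. Without a filter: adipocyte -1.05, nerve 0.13 and myeloid chemokines -0.30. With the filter of 5 CPM: T-cell -0.12, regulatory T -0.76, mast cell 0.78, checkpoint -0.13, regulatory B -0.19 and myeloid chemokines 0.55. With 1 library left out, medians ran from -0.28 to 0.14 (mesenchymal), 0.78 to 1.72 (mesothelial), -0.79 to 0.25 (adipocyte), -0.34 to 0.082 (myeloid chemokines) and -0.25 to 0.33 (extracellular matrix). Myeloid chemokines had -0.052 on log2(FPKM + 1) and, in a setting added after seeing the data, -0.19 with TMM without genes over 100-fold higher. The log2 changes of uncalled genes ran with 1 library left out from -0.28 to 0.053 (Ccl5), -0.12 to 0.31 (Top2a), -0.12 to 0.50 (Cd8a) and -0.19 to 0.61 (S100a8).

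The B cell-like share of liver cells was 0.380% at a UMI minimum of 1000, 0.0747% at 300 (53546 barcodes called) and 0.435% at 3000, and that of primary cells 0 with each library clustered on its own. Primary cells so named were 7 of 2384 at 1000, 6 of 2774 at 300 and 6 of 1960 at 3000. Against 39 of 10250, 40 of 53546 and 23 of 5282 liver cells, the primary share was the higher at 300. At 1000 and 3000 the gap between the sites was smaller than as reported. No B cell-like class was named at a UMI minimum of 500 or mitochondrial maximums of 5% and 20%, so these give no value. Classes absent as reported were named in the liver library with libraries clustered apart (30 plasmacytoid dendritic and 11 hepatocyte-like cells) and at 1000 (20 plasmacytoid). The share of liver B cell-like cells with both Btla and Cd200 was 8.51% when not thinned. Log2 ratios turned in T cell-like cells for Cd8a (0.69 at 300, 0.60 at 500), Cd4 (-1.44, -0.76), Tcf7 (-1.55, -0.93, and -0.27 at 1000), Ccl1 (1.51, 1.53) and Eno3 (-0.11 at 500). They also turned for epithelial Tff1 (-0.33 at 300), Apoe of monocyte or macrophage-like cells (0.16 at Leiden resolution 2, 0.29 at a naming score over 0.5, where Arg1 turned to -0.00035) and neutrophil Mmp9 (-0.80 at 3000). The minimums of 500 and 3000 and the naming score were added after seeing the data. Scrublet marked 0.10% of liver barcodes or fewer at minimums of 300, 500 and 1000 and at both other mitochondrial maximums. As reported it marked 0.220% of primary and 0.919% of liver barcodes, also under the expected 6%, so doublets may remain in every setting.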

Other observations

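Of the tests below, those on few tumor cells, on Tsix and on the Xist exons, on islet cells and on more leukocytes were chosen after the results were seen, and so was the interval used for different tumor cells.

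Primary replicate 1 held adrenal transcripts: Star, of steroid hormone synthesis, was 319 CPM there and 5.89 and 2.51 CPM in primary replicates 2 and 3. Of 11 adrenal genes listed before the test, 9 were highest in that library, with a median ratio of 48.4 to the next-highest library, and Akr1b7 and Slc18a1 were not. Islet cells are argued against by a median ratio of 0.0737 for 6 islet hormone genes. The test asked for a median ratio of at least 5 and, had it been under 2, would have argued against adrenal tissue. Adrenal tissue in this library is therefore a candidate explanation for its Chga, Chgb, Cyp11a1, Dlk1 and Cyp21a1 levels. No biological explanation was tested, as the groups do not set this library apart from the other primary ones.

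Epithelial tumor cell-like single cells held Xist, the RNA of the inactive X chromosome, at 495 CPM (primary) and 363 CPM (liver), with the Y-linked Ddx3y at 3.77 and 2.63 CPM, while Xist was at most 0.616 CPM in the bulk libraries and Epcam at most 5.45 CPM. The bulk libraries held Ddx3y at 49.2 to 108 CPM. Few tumor cells in the bulk tumors would lower all their genes alike, but Xist reached at most 0.00432 of the median share of genes led by these cells, which argues against it for Xist and as the whole cause for Xist and Epcam together. For Epcam alone it is argued against in the primary tumors, where Epcam lay at 0.0132, 0.00411 and 0.0229 of the median share, at most 0.204 of the lowest of the led genes. In the liver tumors it stays open, as Epcam reached 0.132 in replicate 1 and lay at 1.82, 0.471 and 1.13 of the lowest led gene, Krt7, in replicates 1, 2 and 3. Overlap of Xist with Tsix or other genes is argued against, since 87.4% of its exon length is free of their exons, and it would leave Epcam as it is, which reached no more than 0.132. Different tumor cells in the bulk and single-cell samples may be the cause and stay open. Of 28 led genes, 0 lay under 0.1 of the median share in all 6 libraries, with an upper limit of 12.3%. With 28 genes no smaller upper limit was possible, so the bound of 2% set beforehand could not be met. The test therefore cannot argue against different tumor cells, and tumor cells of the same kind would also share such genes.

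The B-cell list rose in the liver tumors by 1.66 (SE 0.33) more on the log2 scale than the T-cell list, in means over the lists, which argues against more leukocytes of every kind as the whole cause. Against Ptprc it rose by 0.92 (SE 0.30) more, which is above 0 but, less 2 SE, not above the 0.5 asked of the T-cell list. B cells of adjoining liver tissue may contribute and cannot be told apart from B cells of the tumor, since the correlation of the list with the share of hepatocyte reads (0.87) rests on 3 liver libraries. The site of the tumor stays among the open explanations, as untested. For the 3787 genes called between sites, 1 of 10 splits of the 6 libraries, the real one, called as many, and the highest other called 0 in edgeR, where the other splits had 45 to 1396 genes at an unadjusted p under 0.05; 10 splits are too few for a share under 0.05.

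Barcodes with under 100 UMIs held Alb at 550 CPM in the primary and 417 CPM in the liver library, and Xist at 224 and 239 CPM. Whether barcodes were swapped between the libraries was not tested.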
